A study of Mus musculus with 4 samples.

How the data were processed

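RNA from NMuMG cells, an epithelial cell line from normal mouse mammary gland, was profiled on 4 long-oligonucleotide arrays of the MEEBO mouse set with 2 dyes on each. Per the labels, every array carried RNA of cells with vector alone in the Cy3 channel and RNA of cells overexpressing ZNF217 in the Cy5 channel. The RNA was extracted with a Qiagen RNeasy kit and amplified and labelled with an Ambion amino allyl kit, per the labels' protocols. The series' design text says that overexpression of ZNF217 was checked by qRT-PCR or Western blot, whose values were not used here.

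The deposited table holds 1 value per probe and array, used here as a log2 ratio of the channels. Neither the log base nor the direction nor the centring of these values is stated in the sources used here. Base 2 is an assumption, based on the range of the deposited log values and common practice for arrays with 2 dyes. A positive value likely means more signal in the ZNF217 channel, because that is channel 2 on every array in the labels and ratios are usually formed as channel 2 over channel 1. Signs below are therefore given as positive or negative log ratios. The background correction, normalization and spot filters that the authors applied are not given in the sources used here. The deposited values have 2 decimals, and some are missing. The intensities behind the ratios were not used here, so a dim spot cannot be told from a bright one, and no filter on signal over background was made.

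All 4 value columns of the table were used and belong to 1 group. Medians per array were 0.12, 0.09, 0.07 and 0.05 as deposited, and means were -0.00119, 0.00316, 0.0267 and 0.0271. A rule written before the data were examined asked for centring if any median lay more than 0.1 from 0, so each array was centred on its own median. This lowered all values of an array by its median and took the mean of each array below 0. Probes measured on at least 3 of the 4 arrays were tested, which left 34479 of 34968 probes and set 489 aside. The mean log ratio of each probe was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intercept only, 2-sided). P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. The vector RNA acts as the reference on each array and has no sample of its own. The sources used here do not say whether 1 vector RNA or several were used: if 1 was shared by the arrays, its own spread is left out of every test, and if each array had its own, that spread is part of the spread between arrays. No array has the dyes exchanged, so a dye effect of a probe cannot be separated from a difference between the RNAs. Nothing in the labels says whether the 4 samples came from separate cultures or transductions, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

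Probe identifiers could not be named. The reference table of 49997 mouse genes contains 0 of the array's identifiers, and no annotation of the array was used here. The planned test per gene and the planned tests of 33 gene lists (mammary lineages, epithelial and mesenchymal genes, signalling pathways, cell cycle, metabolism, stress and markers of other cell types) were therefore not run. The test per probe, which was planned beside them, takes their place. Control probes of the array could not be told from others and were kept in. The rule for naming, fixed before the data were examined, was the 2 identifiers that rose most and the 2 that fell most. For negative ratios these are the 2 with the lowest mean among probes that passed the threshold with the same sign on every array. They are not the lowest of all tested probes, where the lowest mean was -3.63 and did not pass. No positive probe passed, so the 2 with the highest mean and the same sign on every array are given as values.

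The closing block of identifiers used below was set after the calls had been seen. Its start is the point in the identifier order that best splits the probes into 2 stretches by the log of their mean absolute centred ratio plus 0.05, at least 500 probes from either end. The test was also tested on simulated data. In each of 20 rounds, normal noise with each probe's own SD was drawn for 34479 probes, and 200 of them were shifted, 50 at each of 4 sizes. With the comparison of ZNF217 and vector simulated this way, limma called 0.8% of probes shifted by 0.5, 41.9% of those shifted by 1, 82.3% of those shifted by 2 and 92.4% of those shifted by 3 on the log2 scale. It called 3.15 unshifted probes per round on average. The noise was drawn independently for each array, whereas the real arrays 1 and 2 correlated at 0.57 and arrays 3 and 4 at 0.58. The simulation leaves this dependence out, so its rates of detection and of false calls may not hold for these data.

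Alternatives fixed before the data were examined were the values without centring, scaling of the arrays to a common median absolute value, quantile normalization between arrays, other limits on missing values, a minimum mean size of 0.5, robust eBayes, an ordinary one-sample t statistic, array weights, and leaving out each array in turn. Leaving out the closing block, taking off a running median over 501 probes in identifier order, and counting at an adjusted p under 0.10 were added after the data had been seen.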

Results

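The study compared NMuMG mouse mammary epithelial cells that overexpress ZNF217 with the same line carrying vector alone. ZNF217 encodes a zinc finger protein that binds DNA and works with corepressors of transcription, and the gene lies in a region often amplified in breast tumours. The question that the design poses is which expression changes go with ZNF217 in mammary cells. One group of 4 arrays was deposited, each with ZNF217 RNA against vector RNA. The table held 34968 probes, of which 33027 had a value on all 4 arrays. Array 1 had 34727 measured probes, array 2 had 34864, array 3 had 34479 and array 4 had 33242. The probes have identifiers but no gene names in the sources used here, so neither the probe of the mouse gene Zfp217 nor any lineage gene could be read.

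The arrays differed in how widely their log ratios spread. The SD over probes was 0.52 on array 1, 0.57 on array 2, 0.39 on array 3 and 0.38 on array 4. After centring, array 1 had 207 probes at 1 or more and 2553 at -1 or less. Array 2 had 704 and 2017 such probes, array 3 had 192 and 458, and array 4 had 210 and 304. More probes lay in the negative than in the positive tail on each array.

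**Figure D1:**
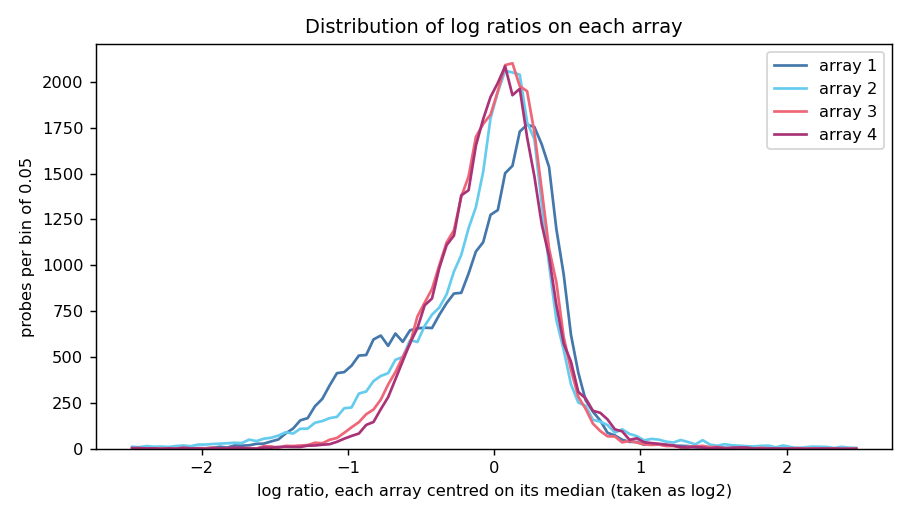
The number of tested probes per bin of 0.05 is plotted against the log ratio (taken as log2) for each array after centring on its median, with the axis limited to the middle of the range. Array 1 has a shoulder of negative ratios and 2553 probes at -1 or less, and arrays 3 and 4 are narrower.

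The log ratio of the ZNF217 and vector channels differed from 0 beyond the spread between arrays at 11 of 34479 probes, and all 11 had negative log ratios. With no dye exchange, these ratios contain any dye effect of the probes. Their mean log ratios ran from -3.34 to -2.03, and each was negative on 4 of 4 arrays. Probe mSQ035864 had the lowest mean among them, -3.34 ± 0.42 (SD, n = 4), with a limma adjusted p of 0.0313 and a 95% interval from -3.76 to -2.91. Probe mSQ036788 followed with -3.14 ± 0.51 (SD, n = 4), the same limma adjusted p of 0.0313 and an interval from -3.63 to -2.65. If the ratios were formed as ZNF217 over vector, these probes gave less signal in the ZNF217 channel. The lowest mean of all tested probes was -3.63, at a probe that did not pass the threshold. The genes or controls that the 11 probes target are not known here.

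No positive log ratio passed the threshold in limma, where the smallest adjusted p of a positive probe was 0.0745, although 2800 positive probes had an unadjusted p under 0.05. The highest mean belonged to probe mSQ016520, at 1.90 ± 1.98 (SD, n = 4), with a limma adjusted p of 0.17. Its value was 4.64 on array 2 and 2.06 on array 1, but 0.36 on array 3 and 0.53 on array 4. Without array 2 its mean was 0.98. Probe mSQ015374 had a mean of 1.63 ± 0.996 (SD, n = 4) and a limma adjusted p of 0.0883, with 0.23 on array 1 and between 1.67 and 2.53 on the other arrays.

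**Figure D2:**
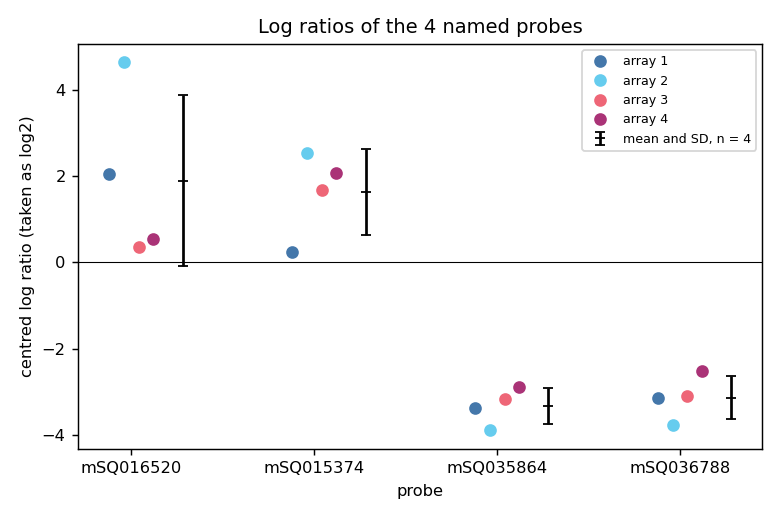
Centred log ratios (taken as log2) of the 4 named probes are shown as 1 point per array, with the mean and SD over the 4 arrays as a black bar. Both negative probes lie at -2.53 or lower on every array, while mSQ016520 ranges from 0.36 to 4.64.

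The count of 11 fell when any array was left out. Without array 1, 2 or 3 limma called 0 probes, with 6512, 7181 and 6519 probes at an unadjusted p under 0.05. Without array 4 it called 6 probes. Without array 1, 2, 3 or 4 the mean of mSQ035864 was -3.32, -3.15, -3.39 and -3.48, and that of mSQ036788 was -3.13, -2.93, -3.15 and -3.34. The ratios of these 2 probes thus changed little. Each of these fits had fewer arrays, so loss of power cannot be told from dependence on the array left out.

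The called probes were not spread over the array's identifiers. All 11 had identifier numbers from 35769 to 36835, near the end of the table's range of 769 to 36862. From number 35731 on, a closing block of 991 probes differed from the rest. Of its 774 tested probes, 46 (5.94%) had a mean log ratio of -1 or less, against 154 of 33705 (0.457%) elsewhere. Leaving out the 11 calls, 35 of its 763 probes (4.59%) did. In the other direction, 0 of the block's 774 tested probes and 26 of the 33705 others had a mean of 1 or more. Such means were so rare elsewhere that 0 in the block does not show a lack of them. The median of the probe means was 0.063 in the block and 0.0025 elsewhere, so the negative probes were a minority of the block. The middle of the block was narrower, with an interquartile range of the probe means of 0.3 against 0.468 elsewhere. The block was drawn after the calls had been seen, and its start was set from the size of the ratios. Its holding all of the calls, its share of large ratios and its narrower middle are therefore descriptions and were not tested. Missing values took 51.0% of the block's probes on array 4 against 3.59% elsewhere, 21.9% against 0.801% on array 3 and 4.74% against 0.168% on array 2, but 0.706% against 0.689% on array 1. Without the block, limma called 0 of 33705 probes, with 8692 at an unadjusted p under 0.05.

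**Figure D3:**
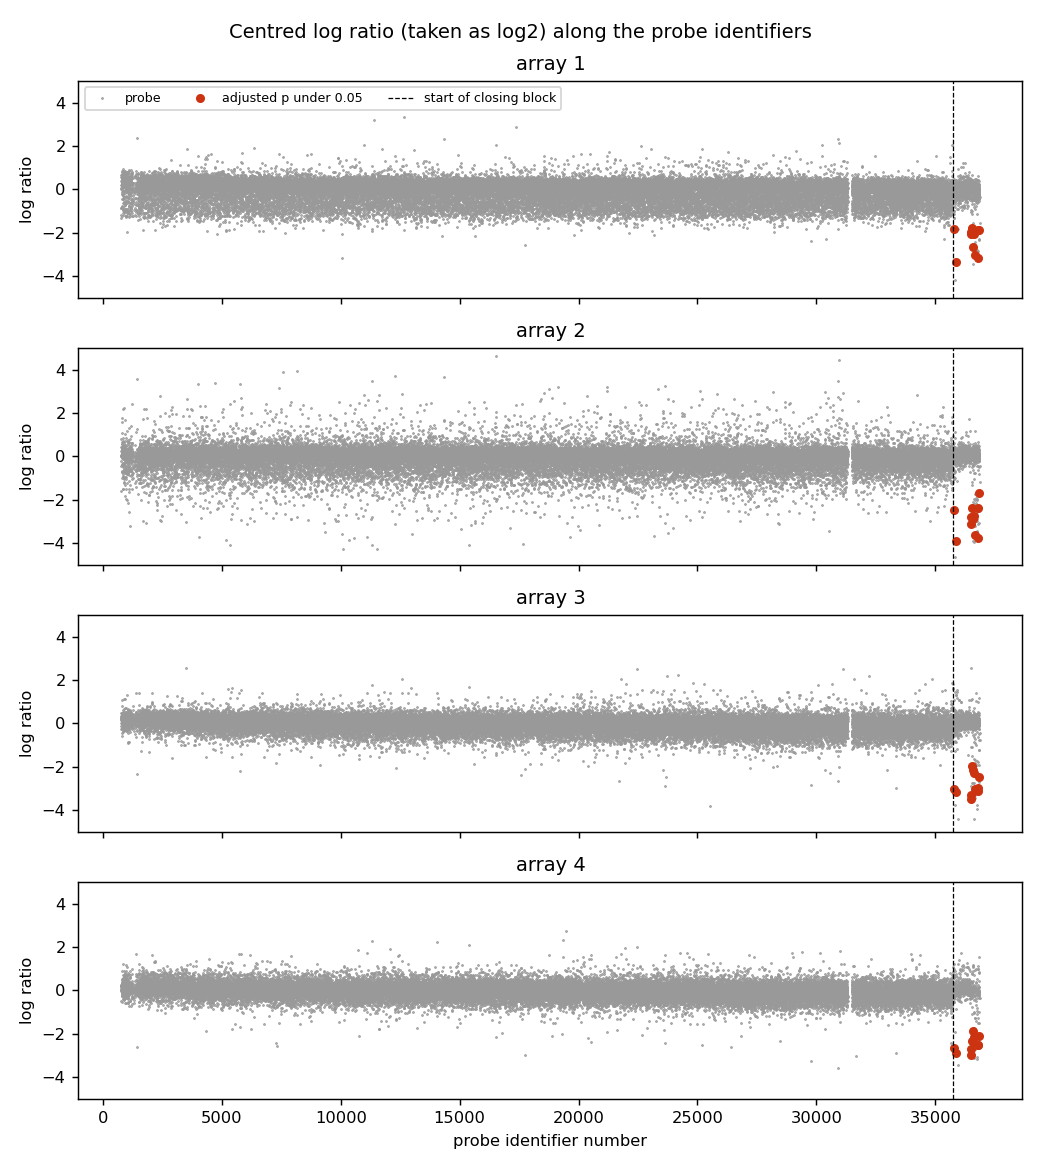
Centred log ratios (taken as log2) of the tested probes are plotted against the number in the probe identifier, with 1 panel per array. Red points are the 11 probes with an adjusted p under 0.05, and all lie right of the dashed line at identifier number 35731 where the closing block starts.

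Beyond the 11 called probes, many probes leaned the same way on all arrays without passing the threshold. The counts below were taken over all probes, with those 11 not left out. Of the 33027 probes measured on every array, 12104 (36.6%) had the same sign on all 4, 5536 positive and 6568 negative, where 4 independent arrays with no difference would give 12.5%. The arrays were not independent, since arrays 1 and 2 shared a sign at 69.6% of these probes, as did arrays 3 and 4. If those pairs were independent of each other, 24.2% would share a sign on all 4. An unadjusted p under 0.05 was reached by 8852 probes (25.7% of those tested), against 1724 expected if no probe differed and the arrays were independent. Of these 8852, 2800 were positive and 6052 negative after centring. On the values as deposited, 10488 probes had an unadjusted p under 0.05 in limma, 5931 positive and 4557 negative. Which sign is more common therefore depends on the centring. With the signs of arrays 3 and 4 turned, 1985 probes still reached an unadjusted p under 0.05. A mean of 1 or more with a positive sign on each measured array was found for 14 probes, and a mean of -1 or less with a negative sign on each for 169. Because the dyes were never exchanged, a lean shared by all arrays contains any dye effect of the probes.

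The arrays did not resemble each other equally. Across probes, the Pearson correlation of log ratios was 0.57 between arrays 1 and 2 and 0.58 between arrays 3 and 4. The other correlations were 0.30 for arrays 1 and 3, 0.23 for arrays 1 and 4, 0.17 for arrays 2 and 3, and 0.13 for arrays 2 and 4. Spearman's rho was 0.54 for both of the closer pairs and between 0.24 and 0.34 for the others. These are correlations across probes, which are not independent replicates, and 6 pairs were computed. No correlation was negative. No pair of arrays held the same values, and each array was counted as 1 sample. The labels give no batch, slide or date that sets these arrays apart.

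**Figure D4:**
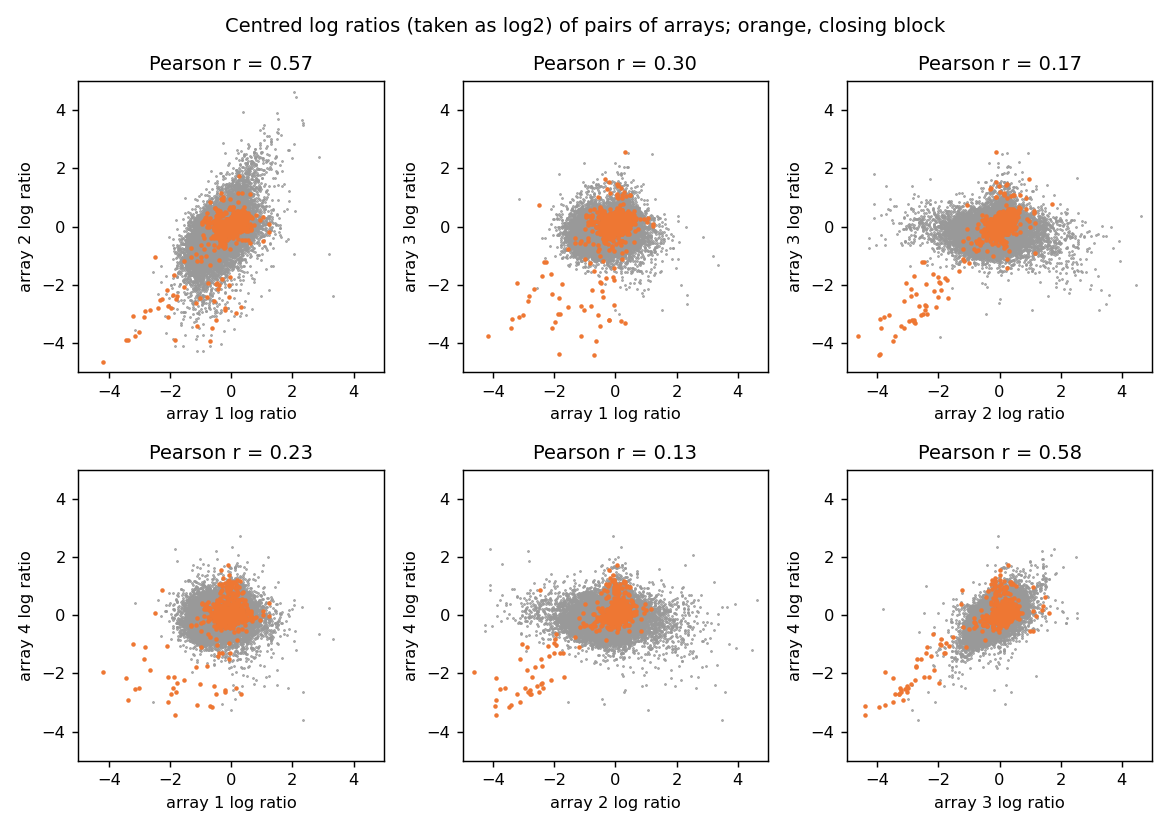
Each panel plots the centred log ratios (taken as log2) of 1 array against another for the tested probes, with the closing block of identifiers in orange and the Pearson correlation over all probes above. Arrays 1 and 2 and arrays 3 and 4 form elongated clouds (0.57 and 0.58), while in the other panels mainly orange points extend along the diagonal.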

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

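The number of probes with a centred log ratio of 1 or more stood apart on array 2, which had 704 against 207, 192 and 210 on arrays 1, 3 and 4. The gap from array 2 to the nearest other array was 0.965 of the whole range, above the 95% critical value of Dixon's test for 4 samples. Chance flags about 1 in 20 such groups of values, and 11 sets of values were looked at. Over single probes, 2151 of 33027 (6.51%) had 1 array standing apart by this measure, against 5% by chance, most often array 1 with 790 probes. Both chance rates assume independent values, whereas arrays 1 and 2, and arrays 3 and 4, correlated with each other. The rate over single probes also assumes equal spread, and the SD over probes was wider on arrays 1 and 2. The 5% is therefore only a rough reference.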

How the results depend on the processing

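The count of 11 called probes stayed between 11 and 16 with the values as deposited, both other limits on missing values, the minimum mean size of 0.5, array weights and the identifier trend taken off, and in each of these all 11 probes remained called. It moved with other settings. Scaling the arrays to a common median absolute value left 0 calls, with a smallest adjusted p of 0.0503. Quantile normalization gave 1123 (14 positive, 1109 negative, 1092 outside the closing block), with all 11 among them. Robust eBayes gave 5, all among the 11. The ordinary one-sample t statistic gave 2, neither among the 11. Leaving out 1 array at a time gave 0 to 6 calls, of which 3 of the 6 without array 4 were among the 11. Leaving out the closing block gave 0, since every call lay in it. For the other moves the cause was not tested. No alternative reversed the sign of a named probe: mSQ035864 ran from -3.48 to -3.15 and lost its call in 5 of 13 alternatives (adjusted p from 0.00532 to 0.202), and mSQ036788 ran from -3.34 to -2.93 and lost its call in 5 of 13 (adjusted p from 0.00532 to 0.207). mSQ015374 and mSQ016520 stayed above the threshold in 14 of 14. The median of the 6 correlations between arrays was 0.264, ranged from 0.169 to 0.299 without 1 array, and moved by less than their SD in every alternative computed. Centring or scaling an array cannot change these correlations, and their SD includes the gap between the closer pairs and the others. This measure therefore says little on how stable the agreement is. The tests per gene and per gene list and their alternatives were not run, because no probe could be named. Each ratio already sets ZNF217 against vector RNA on the same array, so the test of the mean ratio against 0 compared the RNAs within arrays. Whether each array had its own vector RNA is not known, so this may not be a pairing of samples. The test treated the arrays as independent, and no fit that allows for the likeness of arrays 1 and 2 and of arrays 3 and 4 was run. Signal over background is not known, so the limit it sets on dim probes cannot be given.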

Other observations

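The tests of the closing block, the identifier trend, the pairs of arrays and the sign patterns were chosen after the results had been seen, while quantile normalization, the values as deposited, the other scalings and weights, the ordinary t statistic and the left-out arrays were planned. Probes with large ratios on 1 array behaved differently on the others. Outside the closing block, 697 probes had a log ratio of 1 or more on array 2. Of those also measured on array 1, 82.9% were positive there, with a median of 0.39, but on array 3 only 29.1% were positive, with a median of -0.31, and on array 4 only 37.8%, with a median of -0.18. The 174 probes at 1 or more on array 3 were positive on array 4 in 84.9% of cases (median 0.67), on array 1 in 50.9% (median 0.01) and on array 2 in 63.8% (median 0.14). Of the 408 probes at -1 or less on array 3, 90.0% were negative on array 4, while of those measured on array 1 60.2% were negative there, and on array 2 49.8% were. Large negative ratios on array 1 carried over further, since of 2519 probes at -1 or less there 93.5% were negative on array 2, 75.2% on array 3 and 65.8% on array 4. For those on array 2, 66.9% were negative on array 3 and 60.8% on array 4. For those on array 4, 92.1% were negative on array 3, but 53.6% on array 1 and 42.3% on array 2, among probes measured there. Probes at 1 or more on array 1 were positive in 75.9% of cases on array 2, but in 26.1% on array 3 and 32.7% on array 4.

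The 11 calls all lie in the closing block of identifiers. All 11 remained called once a running median in identifier order was taken off. Their means ran from -3.34 to -2.03. For identifier numbers from 35001 to 36000, the medians as deposited were 0, 0.03, -0.08 and -0.09 on arrays 1 to 4. From 36001 on they were 0.15, 0.17, 0.15 and 0.12. Taking off a trend this small could barely change the calls' ratios, so their staying called does not bear on the cause. The small size of these medians itself argues against the trend as the source of such large ratios. Whether the block holds a class of probes of its own, such as controls, stays open. Its share of missing values was more than 2 times that elsewhere on 3 of the 4 arrays, but not on array 1. The share of missing values did not itself set the block's start. Each probe's mean absolute ratio was taken over its measured arrays only, though, so missing values could have affected the start. Pearson correlations were higher in the block than outside it for all 6 pairs of arrays, for example 0.70 against 0.57 for arrays 1 and 2 and 0.87 against 0.13 for arrays 2 and 3, but Spearman's rho was lower in the block for 4 of the 6. The calls, with large negative ratios on every array, are part of the block's Pearson values, which were not computed without them. The higher values are therefore no separate evidence on the block. As 0 arrays had vector RNA in Cy5, dye bias and a difference between the RNAs cannot be told apart for these 11 probes. The 8 sign patterns of 4 arrays are too few for a share under 0.05: 1 pattern, the real one, gave as many calls, and the highest of the other patterns gave 0.

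Arrays 1 and 2, and arrays 3 and 4, correlated with each other more than across. The trend along the identifiers is argued against as the cause, since the lower of the within-pair correlations was still 0.555 once it was taken off. So is the closing block, outside which it was 0.561, and so are a few extreme probes, since the lower rank correlation was 0.535. The labels describe all 4 samples alike, so no biological explanation was tested, and shared RNA, a separate infection or a shared day of hybridisation stay open. If arrays of a pair shared RNA, the 4 arrays would hold fewer independent samples than the tests assume.

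Quantile normalization raised the count of calls to 1123. Of the 1112 added probes, 1099 had an adjusted p from 0.05 to under 0.10 before it, a range that held 2146 probes. The cause of the rise was not tested. At an adjusted p under 0.10 limma would call 2157 probes, 136 positive and 2021 negative, a limit chosen after the data had been seen. That count was 16 on the values as deposited, 2 by the ordinary t statistic, 942 with the identifier trend taken off, and 15, 4, 0 and 7 without array 1, 2, 3 or 4. It was 3368 with the arrays scaled to a common median absolute value, 3936 with quantile normalization and 4219 with array weights. With the sign of 1 or more arrays turned, the highest count under 0.10 was 3. As all correlations between arrays were positive, turning signs would lower the count in any case. That count is therefore no measure of what chance would give.

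Log ratios as deposited, before centring, were lower at higher identifiers over most of the range on all arrays, as a median per 1000 identifier numbers from 0.30 to 0.00 on array 1 and from 0.30 to -0.08 on array 3 between the numbers starting at 1001 and those starting at 35001. In the last stretch, of 757 probes from 36001 on, the medians were higher again, at 0.15, 0.17, 0.15 and 0.12 on arrays 1 to 4. With that trend off, values 96 identifiers apart correlated at 0.17 on array 4 and at 0.03 to 0.07 on the other arrays, against 0.04 on array 4 for values 50 apart.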
